A study of Mus musculus with 21 samples.

How the data were processed

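RNA was measured in hearts of adult male wild-type mice given polystyrene nanoplastics or distilled water for 8 weeks, per the labels. The hearts were rinsed with cold buffer and divided into an atrial, a right ventricular and a left ventricular section, and RNA was isolated with TRIZOL, per the labels' protocols. Libraries were made with the Singleron AccuraCode plate kit, per the labels' protocols: polyadenylated RNA was captured on oligo-dT beads, a barcode for each well was added by template switching at the 5' end during reverse transcription, and the wells were then pooled for amplification. Reads were paired-end, 150 bp long, from an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name STAR, a read aligner, without a version. The genome build, the gene annotation, the counting program, the use of strand and the use of molecular identifiers are not given in the sources used here. The amplification before pooled sequencing makes this gap matter: counts of reads that are copies of the same molecule are not independent, so counting intervals and floors cover counting error only.

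The values are raw counts per gene symbol, as the authors deposited them in a single table of 20960 genes and 21 libraries. All columns were matched to a sample by the library names in the labels. The values are whole numbers, no gene has a total of 0, and none of the 210 pairs of libraries is identical. The chi-square per degree of freedom was at least 2.475 between pairs without the library of 4662 counts, and as low as 1.129 with it, where so few counts leave little to compare. Gene names were used as the table gives them, and no coordinates are printed because the build is not given. The GENCODE M21 annotation, which holds 20504 of the symbols, served only for transcript lengths and gene types. A gene's length is that of its longest annotated transcript, and no length of RNA was measured. Of the genes tested in the whole heart, 99.1% have a length. Genes with near-identical copies (the hemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, ribosomal protein pseudogenes, and pseudogene loci such as Gm4149, Gm11808 and Pdcd5-ps) and genes that overlap others or lie antisense to them are uncertain, since it is not stated how shared reads were counted.

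Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each comparison kept the genes that pass filterByExpr with its defaults, scaled libraries by the trimmed mean of M-values (TMM), and used the robust quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. Adjusted p-values in the text come from this test unless another tool is named. Levels are CPM, a gene's share of its library's counts on the usual fixed scale, scaled by TMM for named genes and by the library total for marker genes and library measures. Nanoplastics and control mice were compared within each section and in the whole heart, where the counts of a mouse's 3 sections were summed to keep 1 value per mouse. Sections were compared in pairs with the mouse as a block, since the sections of a mouse come from the same animal. The difference of the nanoplastics effect between sections was tested as an interaction over the 21 libraries with the mouse as a block. Replicate numbers name different animals in the treatment groups, so the treatment comparisons have no block.

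Before the data were examined, 39 gene lists with 883 genes were fixed. They cover heart muscle, rhythm and calcium, metabolism, stress pathways, and markers of other cell types. Lists with at least 4 tested genes were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. Library measures were compared with exact two-sided permutation tests over all 35 splits of the 7 mice, adjusted over 32 tests. Named genes follow a rule fixed at the same time: in each treatment comparison the 10 called genes with the largest rise and the 10 with the largest fall, at a mean of at least 10 counts and without predicted genes named only by number. Added were up to 4 called members per list and direction, 17 fixed genes of heart stress, rhythm and fibrosis, and the 10 genes with the smallest p where fewer than 10 were called. Sections took 8 genes per direction plus fixed section markers. Interaction results name the 10 smallest p.

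The steps were tested on simulated counts with 200 changed genes at the real depths, without differences between mice beyond the fitted spread. For 2-fold and 4-fold changes, edgeR recovered 49% and 89% of genes in the atria (5317 genes), 61% and 88% in the right ventricle (4262), 65% and 90% in the left ventricle (5151) and 65% and 99% in the whole heart (8359). It recovered 90% and 90% between atria and left ventricle (5050 genes) and 84% and 86% between atria and right ventricle (4877). It recovered 88% and 88% between the ventricles (4720), and 36% and 85% for the interaction (6122). Of all calls, the false ones were 16 of 154 in the atria, 4 of 153 in the right and 7 of 162 in the left ventricle. They were 15 of 179 in the whole heart and 14 of 135 for the interaction. Between sections they were 7 of 187 (atria and left ventricle), 14 of 184 (atria and right ventricle) and 2 of 178 (the ventricles). Their share exceeded the adjusted p threshold in the atria, whole heart, atria against right ventricle and interaction. Alternatives fixed with the design were other scalings (DESeq2 size factors, library totals alone), other filters (none, a mean of at least 20 counts), other tools (DESeq2, limma-voom), a block by mouse number, an atrial-against-ventricular marker score as a covariate (the dissection covariate), removal of mitochondrially encoded genes, other ways to combine sections, and leaving out each mouse. No sample was left out of the comparisons as designed.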

Results

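The series profiled gene expression in the hearts of adult male wild-type mice after 8 weeks of exposure to polystyrene nanoplastics, plastic particles of nanometre size, or to distilled water. Each heart was divided into a section labelled atrial, a right ventricular section and a left ventricular section, and each section gave its own bulk RNA library. There were 4 nanoplastics mice and 3 control mice, which makes 21 libraries. The title of the series links nanoplastics to disturbed rhythm in human heart muscle cells, and the mouse hearts address which transcripts differ in the intact heart and in which section.

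The control atrial libraries held 1053232, 990954 and 1286523 counts, the control right ventricular libraries 2042568, 1791758 and 1333133, and the control left ventricular libraries 2439314, 2128263 and 413436. The nanoplastics atrial libraries held 841786, 1290936, 887249 and 2275813 counts, and the nanoplastics left ventricular libraries 1689813, 1041109, 1214289 and 924621. The nanoplastics right ventricular libraries held 523089, 4662, 813585 and 438053 counts. In the library of 4662 counts, the right ventricle of nanoplastics mouse 2, only 1462 genes were detected and 1 count equals 214.5 CPM, so a gene with no count there can lie anywhere up to 643.5 CPM (3 counts). Right ventricular totals were lower in the nanoplastics group, 444800 ± 334600 against 1722000 ± 359800 (SD, n = 4 and 3; exact two-sided permutation p = 0.0286, adjusted p = 0.183 over 32 library measures).

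Counts in the nanoplastics libraries came more from genes with short annotated transcripts. The median annotated transcript length per count, mitochondrially encoded genes left out, was compared by section. In the atria it was 1495 ± 118.2 nt in the nanoplastics group and 1743 ± 49.94 nt in the controls (SD, n = 4 and 3, exact permutation p = 0.0286). In the left ventricle it was 1530 ± 46.77 against 1672 ± 66.97 nt (exact p = 0.0571). It was 1604 ± 155.9 against 1741 ± 46.97 nt in the right ventricle (exact p = 0.2). There the library of 4662 counts stood at 1825 nt. The other nanoplastics libraries stood at 1473, 1596 and 1521 nt, and the controls at 1698, 1733 and 1791 nt. Whole-heart library measures are unweighted means over a mouse's 3 libraries, not values of the summed counts, so the library of 4662 counts has a full share. The length was 1543 ± 86.86 against 1718 ± 36.67 nt by this mean (exact p = 0.0571). The share of counts in pseudogenes, as the same mean over a mouse's libraries, was 1.28 ± 0.0881% in nanoplastics mice and 1.083 ± 0.04774% in controls (SD, n = 4 and 3, exact permutation p = 0.0286). None of the 32 measures passed adjustment, where the smallest adjusted p was 0.183.

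**Figure D1:**
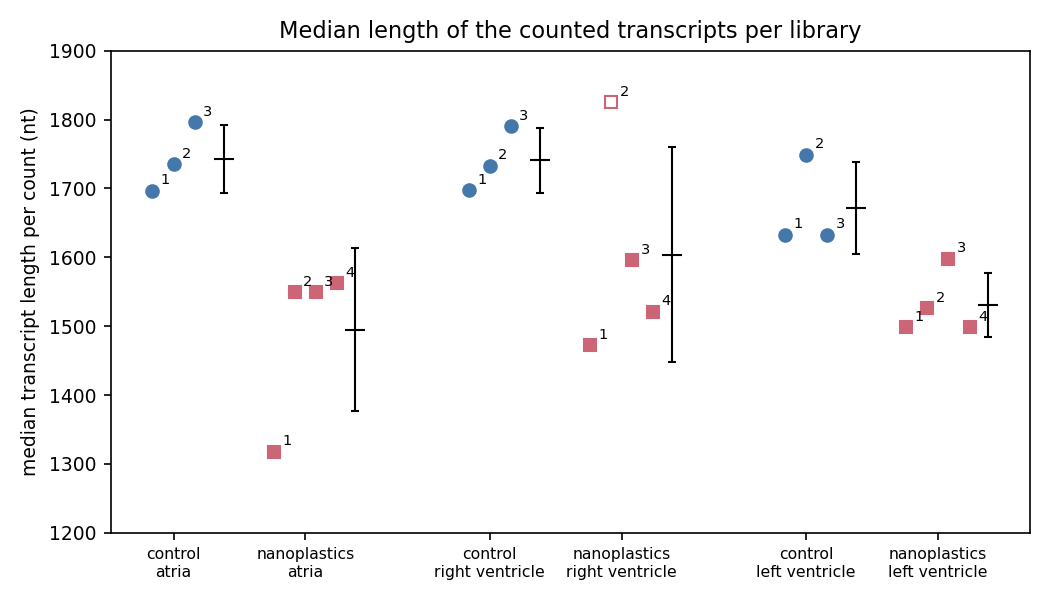
Median annotated transcript length per count in nucleotides (vertical axis, which does not start at 0) for each library, by section and treatment. Numbers name the mouse, bars show mean ± SD, and the open square is the library of 4662 counts. Nanoplastics libraries lie between 1318 and 1598 nt apart from that library at 1825 nt, and controls between 1633 and 1796 nt.

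Most libraries labelled atrial section held few transcripts of atrial muscle. Myl7, the atrial myosin regulatory light chain, ranged from 3.381 to 14170 CPM over the 7 atrial libraries with a median of 41.06, and had medians of 3.289 CPM in the left and 3.349 CPM in the right ventricle. Sln, which encodes the atrial calcium pump regulator sarcolipin, ranged from 1.127 to 20700 CPM in the atria with a median of 10.1, against medians of 4.229 CPM in the left and 3 CPM in the right ventricle. Myl2, the ventricular counterpart of Myl7, had a median of 10680 CPM in the atria (range 7814 to 12270), 9752 CPM in the left ventricle and 9001 CPM in the right ventricle. The ventricular transcription factor gene Irx4 had medians of 4.747, 5.408 and 2.448 CPM in atria, left and right ventricle, and Hey2 1.549, 0.8199 and 0.5581 CPM. Bmp10, a growth factor gene of atrial muscle, had no count in any atrial library, Gja5 and the pacemaker channel gene Hcn4 had medians of 0 there, and the atrial potassium channel gene Kcnj3 had medians of 23.74, 19.35 and 12.29 CPM. The summed level of Myl7, Myl4 and Sln was 38990 CPM in the atria of nanoplastics mouse 1 and 2969 CPM in those of mouse 4, 66.62 and 10.14 CPM in mice 2 and 3, and 19.94, 296.7 and 52.86 CPM in the control atria. It reached 1605 CPM in the left ventricle of nanoplastics mouse 4. The libraries are therefore called by their label in what follows, and a difference between "atria" and ventricles is a difference between sections so labelled.

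**Figure D2:**
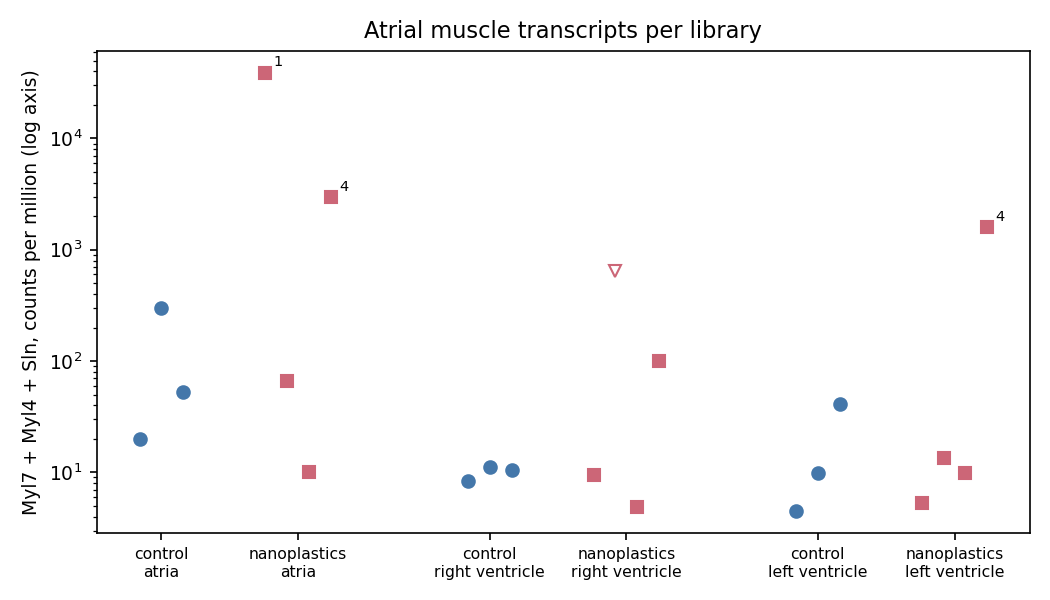
Summed CPM of the atrial muscle transcripts Myl7, Myl4 and Sln (log axis) in each library, by section and treatment; numbers name the mouse where the sum exceeds 1000 CPM. The open triangle is the library of 4662 counts, which had no such count and is drawn at its floor of 643.5 CPM. The atria of nanoplastics mice 1 and 4 and the left ventricle of mouse 4 stand at 38990, 2969 and 1605 CPM, and the other libraries with counts at or under 296.7 CPM.

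The whole heart, where each mouse is a single value, had the largest set of calls. Cox6a2, the heart and skeletal muscle subunit of cytochrome c oxidase, rose from 6610 ± 749 CPM in 3 controls to 12100 ± 1830 CPM in 4 nanoplastics mice (SD; log2 change 0.87, SE 0.13, adjusted p = 0.00681). Rgs2, a regulator that shortens signalling by G protein-coupled receptors, rose from 31.8 ± 2.47 to 67.2 ± 21.8 CPM (log2 change 1.08, SE 0.20, adjusted p = 0.0183). Neat1, the long noncoding RNA that builds nuclear paraspeckles, fell from 39.3 ± 3.34 to 15.6 ± 5.52 CPM (log2 change -1.33, SE 0.21, adjusted p = 0.0102). Ppara, the nuclear receptor that switches on fatty acid oxidation genes, fell from 12.4 ± 1.16 to 5.11 ± 1.31 CPM (-1.31, SE 0.24, adjusted p = 0.0183). In all, 152 genes rose and 65 fell among 8485 tested, and 1541 had an unadjusted p under 0.05, a balance that turned to 43 higher and 754 lower with library totals alone. Other large rises were those of Dkk3, a secreted Wnt modulator (log2 change 1.78, SE 0.46), Sertad1 (1.19, SE 0.32), the matrix proteins Fbln1 (1.09, SE 0.23) and Efemp1 (0.86, SE 0.22). They were followed by Inmt (0.99, SE 0.23), Csnk2b (0.85, SE 0.21) and the chemerin gene Rarres2 (0.85, SE 0.19), with adjusted p from 0.0256 to 0.0496. Averaging the sections with equal weight brought these log2 changes to 0.66 (Sertad1), 0.47 (Dkk3), 0.42 (Fbln1), 0.40 (Efemp1), 0.37 (Inmt), 0.36 (Csnk2b) and 0.18 (Rarres2), with adjusted p of at least 0.638, but it also moved the median of all genes from -0.03 to -0.3, so a part of each drop is shared by all genes. This average gives the library of 4662 counts, with 1462 genes detected, the same weight as the deeper libraries of its mouse. Genes without a count there enter as low values, so the drops do not measure the mix of sections alone. Dkk3, highest in atrial libraries, had 10.17 CPM in nanoplastics mouse 1, without which its log2 change was 1.35 (adjusted p = 0.163), and it was called in 7 of 19 alternatives. The largest falls besides Neat1 and Ppara were in Yrdc, which modifies tRNA (-2.33, SE 0.45), and B3gat3, an enzyme of glycosaminoglycan synthesis (-1.66, SE 0.33). Next came Art5 (-1.43, SE 0.34), the SUMO ligase Pias4 (-1.20, SE 0.31), Lsmem2 (-1.16, SE 0.24), Usp40 (-1.07, SE 0.29), Ankrd9 (-1.06, SE 0.26) and Tom1l2 (-1.05, SE 0.28), with adjusted p from 0.0194 to 0.0488.

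**Figure D3:**
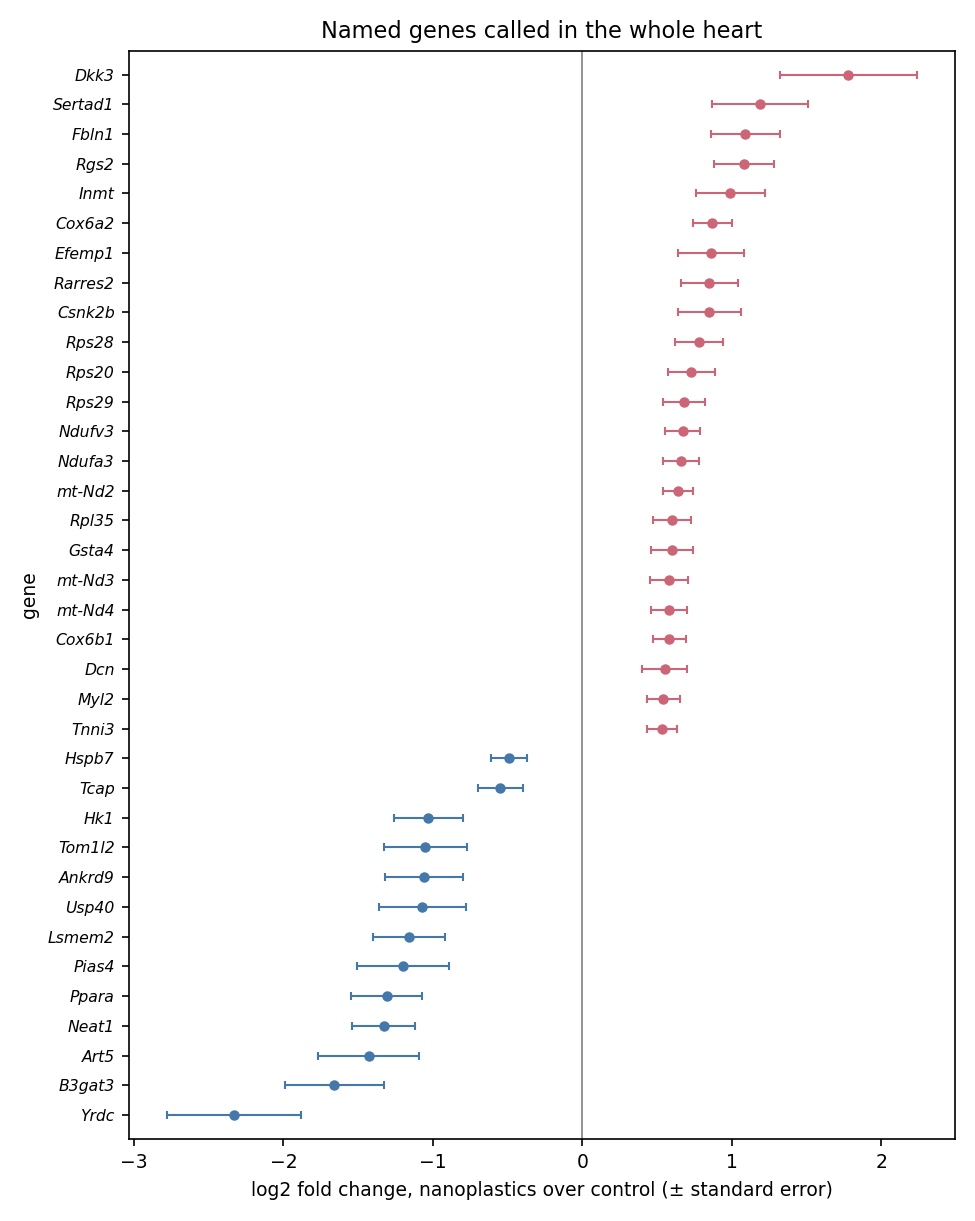
Log2 fold change (horizontal axis, nanoplastics over control, whole heart, n = 4 and 3 mice) with standard error for genes called by edgeR, red for higher and blue for lower. Changes run from 1.78 for Dkk3 to -2.33 for Yrdc.

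Protein synthesis and energy genes were among those that rose. Of 55 tested ribosomal protein genes, 27 rose, none fell and the rest did not pass, and 44 rose adjusted over the list alone, among them Rps28 (log2 change 0.78, SE 0.16), Rps20 (0.73, SE 0.16), Rps29 (0.68, SE 0.14) and Rpl35 (0.60, SE 0.13). The list rose against other genes by camera at its preset correlation (adjusted p = 8.82e-26; adjusted p = 0.563 with an estimated correlation). Of 76 nuclear genes of oxidative phosphorylation, 19 rose, none fell and the rest did not pass, and 45 rose adjusted over the list alone. They include Cox6a2, the complex I subunits Ndufv3 (0.67, SE 0.12) and Ndufa3 (0.66, SE 0.12) and Cox6b1 (0.58, SE 0.11; camera adjusted p = 3.58e-15; adjusted p = 0.501 with an estimated correlation). Of 9 genes encoded in mitochondrial DNA, 3 rose and none fell, mt-Nd2 (0.64, SE 0.10), mt-Nd4 (0.58, SE 0.12) and mt-Nd3 (0.58, SE 0.13), and 6 rose adjusted over the list alone (camera adjusted p = 0.00622; adjusted p = 0.743 with an estimated correlation). These groups moved with transcript length: of the 1682 shortest genes (57 to 1644 nt) 119 rose and 10 fell, and of the 1681 longest genes (5063 to 123179 nt) 1 rose and 9 fell. With the trend on length removed from each library, an alternative chosen after seeing the data, the camera adjusted p was 0.000269 for ribosomal proteins, 0.942 for nuclear oxidative phosphorylation and 0.865 for mitochondrially encoded genes. Without control mouse 3 the mitochondrially encoded list had an adjusted p of 0.195. Its median of 0.32 became 0.08 with library totals alone. All mitochondrially encoded genes together took 27.05 ± 1.746% of counts in nanoplastics mice and 26.18 ± 2.673% in controls, as means over a mouse's libraries (SD, n = 4 and 3, exact permutation p = 0.686).

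Contractile genes were mixed. Of 25 sarcomere genes, Tnni3, the cardiac troponin I gene (log2 change 0.53, SE 0.10), and Myl2 (0.54, SE 0.11) rose, the titin cap gene Tcap fell (-0.55, SE 0.15), and 3 rose and 1 fell adjusted over the list alone. The sarcomere list passed camera as higher (adjusted p = 0.0144; adjusted p = 0.743 with an estimated correlation), and its median of 0.23 became -0.02 when libraries were scaled by their totals alone. That scaling put the median of all genes at -0.27 on the log2 scale against -0.03 with TMM, so changes are given relative to the other genes. Without control mouse 1 the sarcomere adjusted p was 0.132 and without nanoplastics mouse 4 it was 0.104. Of 10 atrial muscle markers Dkk3 alone rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0343; adjusted p = 0.851 with an estimated correlation). The call on that list moved with the atrial-rich libraries: the adjusted p was 0.105 without nanoplastics mouse 1, 0.091 without nanoplastics mouse 4, 0.074 without control mouse 3, and 0.801 without the atria of nanoplastics mouse 1 and the right ventricle of mouse 2. Of 10 ventricular markers only Myl2 rose, also adjusted over the list alone (camera adjusted p = 0.921).

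Ion channel and calcium genes, the machinery of the heartbeat, gave no call over all genes. Of 24 channel and pump genes none passed over all genes (camera adjusted p = 0.0893). Rhythm genes fixed in advance had values of -0.81 for Kcnh2 (SE 0.38, adjusted p = 0.258), -0.15 for Kcnq1, -0.04 for Kcnj2 and 0.01 for Cacna1c. Values were 0.09 for Ryr2, 0.14 for Atp2a2, 0.07 for Pln, -0.37 for Camk2d (SE 0.15, adjusted p = 0.191) and -0.39 for the connexin gene Gja1 (SE 0.13, adjusted p = 0.122). With library totals alone Cacna1c, Ryr2, Atp2a2 and Pln turned negative. Of 21 calcium handling genes none passed over all genes, and 2 rose (S100a1 and Trdn) and 1 fell (Jph2) adjusted over the list alone (camera adjusted p = 0.921). The natriuretic peptide gene Nppa had a log2 value of 3.57 (SE 1.84, adjusted p = 0.402) that rested on mouse 1, at 7998 CPM against at most 362.4 CPM in the other nanoplastics mice. Nppb had 0.02, Myh6 0.42 (adjusted p = 0.494) and Myh7 0.53 (adjusted p = 0.247), and Hmox1 did not pass the count filter.

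Matrix and fibroblast genes were higher and p53 genes lower as lists, with few genes called singly. Of 28 extracellular matrix genes the decorin gene Dcn rose (log2 change 0.55, SE 0.15). Adjusted over the list alone, Col1a1, Col1a2 and Dcn rose and the collagen chaperone gene Serpinh1 fell (camera adjusted p = 0.000972; adjusted p = 0.501 with an estimated correlation). Of 15 fibroblast markers Dcn rose and, adjusted over the list alone, Col1a1, Dcn and Pdgfra rose (camera adjusted p = 0.00594; adjusted p = 0.501 with an estimated correlation). The fibroblast median, 0.24, was -0.01 with library totals alone. Without the atria of nanoplastics mouse 1 and the right ventricle of mouse 2 these lists had adjusted p of 0.173 and 0.121. The sections entered the sums in unlike shares: atria gave 43.95 ± 17.56% of a nanoplastics mouse's counts and 27.21 ± 13.18% of a control's, and the right ventricle 14.32 ± 11.51% and 39.11 ± 4.196% (SD, n = 4 and 3; exact permutation p = 0.229 and 0.0571). Matrix and fibroblast genes were higher in atrial sections than in the left ventricle (median 0.69 and 0.52). With sections at equal weight, a test chosen after seeing the data, matrix genes had an adjusted p of 0.0313 and fibroblast markers 0.265. The library of 4662 counts has a full share in this test too. Of 14 p53 and apoptosis genes none passed over all genes and Cdkn1a and Gadd45a, which arrest the cell cycle, fell adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.501 with an estimated correlation; adjusted p = 0.0731 without control mouse 1). Single calls in other lists were a fall of the small heat shock protein gene Hspb7 (-0.49, SE 0.12) among 13 cardiac stress genes, of Hk1 (-1.03, SE 0.23) among 20 glycolysis genes, and of Ppara among 32 fatty acid oxidation genes. Gsta4 rose (0.60, SE 0.14) among 27 oxidative stress genes, of which 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0737). None of the 12 inflammatory, 21 interferon, 15 endoplasmic reticulum stress, 14 heat shock, 17 macrophage or 17 endothelial genes passed over all genes, with camera adjusted p from 0.234 to 0.921. By median, mean and test, 4 of the 31 lists tested differed in sign (interferon response, glycolysis, endoplasmic reticulum stress and immediate early genes), none of them called.

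The lists that passed in the whole heart, 7 higher and 1 lower of 31, all lost the call with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in the same direction without comparing them with other genes, called none of the lists, and its mixed form, which counts change in either direction, called 5. The count of 217 genes fell to 0 without control mouse 2, to 27 without control mouse 3, and to 32, 26 and 135 without nanoplastics mice 1, 2 and 4. It was 38 (15 higher, 23 lower) with the length trend removed, and 0 both with the dissection covariate and with sections averaged at equal weight. The equal weights give the library of 4662 counts a full share of its mouse. The covariate also ended the list call of p53 genes (adjusted p = 0.157); the covariate is computed from atrial and ventricular markers, some of them sarcomere genes, so its values for those lists decide nothing. Without the atria of nanoplastics mouse 1 and the right ventricle of mouse 2 the count was 222.

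In the right ventricle, Nppa, the atrial natriuretic peptide gene that ventricles express under load, rose (log2 change 1.08, SE 0.25, adjusted p = 0.00857), at 515 ± 58.5 CPM in 3 nanoplastics libraries against 233 ± 96.3 CPM in 3 controls (SD). Levels in this section leave out the library of 4662 counts, while fold changes include it as designed. Myh7, the slow myosin heavy chain of fetal and stressed ventricles, rose by 0.97 (SE 0.25, adjusted p = 0.0234), from 40.8 ± 12.6 to 82.2 ± 32.5 CPM. Of 21 alternatives, 11 called Nppa and 7 called Myh7. Nppb, another stress gene fixed in advance, was level, at 676 ± 273 CPM against 666 ± 155 CPM in controls. Neat1 fell (-1.35, SE 0.33, adjusted p = 0.0112), from 47.2 ± 1.65 to 18.4 ± 11.8 CPM, as did Pfdn2 (-1.45, SE 0.36) and Pfdn6 (-1.27, SE 0.29), subunits of the prefoldin chaperone, Pfdn2 from 37.7 ± 4.38 to 14 ± 0.241 CPM. In all, 27 genes rose and 12 fell of 4489 tested, and 606 had an unadjusted p under 0.05. The balance turned to 25 higher and 48 lower with DESeq2 size factors and to 11 higher and 223 lower with library totals alone. Cytl1, a secreted factor, rose 2.82-fold, from 16 ± 4.87 to 48.7 ± 15.8 CPM (adjusted p = 0.000851). The other named rises were Csnk2b (1.31, SE 0.26), the nuclear matrix protein gene Matr3 (1.29, SE 0.31), Ptov1 (1.27, SE 0.31), Pdcd5-ps (1.21, SE 0.29), Scgb1c1 (1.19, SE 0.24), Apod (1.12, SE 0.30), Nfib (1.08, SE 0.26) and Cenpf (1.03, SE 0.25). The rise of Ptov1 rested on mouse 4, at 102.7 CPM with the next nanoplastics library at 22.17 CPM and controls at 18.2 ± 1.34 CPM. For the typical gene of this section, edgeR took the spread from the trend over all genes, not from the gene's own values. A gene that is uneven between libraries can therefore be called. The other falls were in Abcf3 (-1.97, SE 0.53), Tmem47 (-1.87, SE 0.46), Fgl2 (-1.42, SE 0.40), the chemokine gene Ccl8 (-1.26, SE 0.33), Arl6ip1 (-1.18, SE 0.31), Egln3, an oxygen sensor (-1.18, SE 0.31), Oaz2 (-1.16, SE 0.29) and the pericyte gene Rgs5 (-0.87, SE 0.24).

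**Figure D4:**
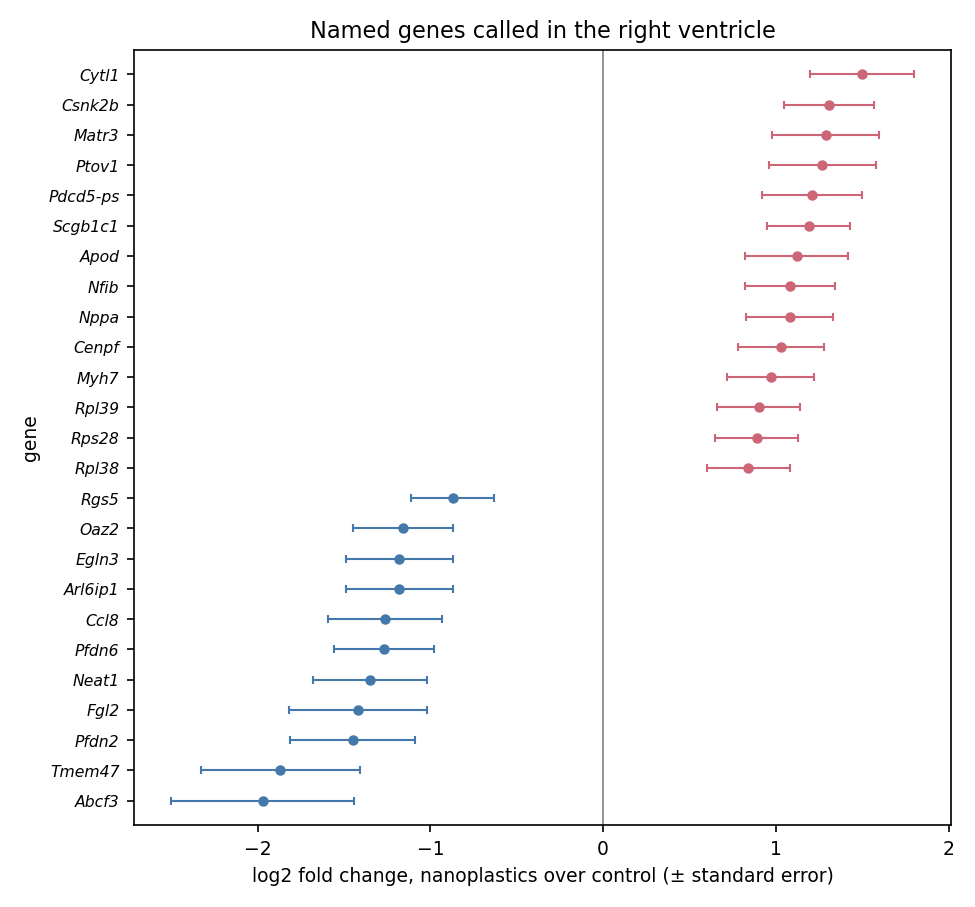
Log2 fold change (horizontal axis, nanoplastics over control, right ventricle, n = 4 and 3 libraries) with standard error for the named genes called by edgeR, red for higher and blue for lower. Changes run from Cytl1 as the largest rise to Abcf3, at -1.97, as the largest fall.

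Ribosomal proteins were the single list of 26 to pass in the right ventricle: of 55 genes 3 rose (Rpl39, 0.90, Rps28, 0.89, and Rpl38, 0.84, each SE 0.24), none fell, and 9 rose adjusted over the list alone (camera adjusted p = 1.02e-13; adjusted p = 0.999 with an estimated correlation). With the length trend removed its adjusted p was 0.319, and with the dissection covariate 0.0781. Nppa and Myh7 were the 2 calls among 10 cardiac stress genes, over all genes and adjusted over the list alone (camera adjusted p = 0.997), and none of 15 channel genes passed, with Atp1b1 lower adjusted over the list alone. The count of 39 genes was 68 without the library of 4662 counts (23 of the 39 were called again), 175 without nanoplastics mouse 3 and 18 without mouse 1, and 4, 17 and 20 without control mice 1, 2 and 3. DESeq2 and limma-voom each called 0, but 172 and 79 without that library, and the covariate left 3 genes, all lower. The number of lists rose to 3, 3, 3, 4 and 2 without control mice 1 and 2 and nanoplastics mice 1, 2 and 3.

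In the left ventricle, the mitochondrially encoded complex I gene mt-Nd4 (log2 change 0.68, SE 0.13; 11500 ± 854 CPM in 3 controls and 18400 ± 2980 CPM in 4 nanoplastics libraries, SD) rose. So did mt-Nd2 (0.65, SE 0.12; 15400 ± 1470 and 24100 ± 1610 CPM), and Neat1 fell (-1.74, SE 0.32; 32 ± 10 and 10.9 ± 6.2 CPM), each with an adjusted p of 0.0414. These were the 3 calls among 5440 genes, with 768 at an unadjusted p under 0.05. Next by p, not past the threshold, were the ubiquitin ligase gene Stub1 (-0.88), Serpinh1 (-0.99), Rhobtb1 (-1.39), Mid1ip1 (-1.32), Esrra, a nuclear receptor of mitochondrial genes (-1.35), the titin gene Ttn (0.73) and C1qbp (-0.78), with adjusted p of 0.0773 for all but C1qbp at 0.0776. Of 76 nuclear oxidative phosphorylation genes none passed over all genes and 29 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.13e-13), and of 55 ribosomal genes 0 and 19 rose (3.62e-13). Of 8 mitochondrially encoded genes 2 rose, 3 adjusted over the list alone (camera adjusted p = 0.00155), and of 23 sarcomere genes Myl2, Tnni3 and Ttn rose adjusted over the list alone (camera adjusted p = 0.00155). The mitochondrially encoded median of 0.31 became 0.13 with library totals alone. All mitochondrially encoded genes together took 29.45 ± 3.692% of nanoplastics and 28.36 ± 4.858% of control counts (SD, n = 4 and 3, exact permutation p = 0.743). The 8 p53 genes were lower as a list with none called (camera adjusted p = 0.0336), and for all 5 lists the adjusted p was 0.701 with an estimated correlation. Annotated lengths per count were shorter here too (1530 against 1672 nt), and with the length trend removed the 4 higher lists had adjusted p from 0.104 to 0.685 and p53 0.202. The p53 call ended without control mouse 1 (0.374) and nanoplastics mouse 1 (0.0508), and the mitochondrially encoded list had 0.0506 without control mouse 3. The gene count of 3 became 1, 0 and 21 without control mice 1, 2 and 3, and 0 without nanoplastics mouse 1 or 3. DESeq2 called 155 genes, and the removal of mitochondrially encoded genes, a filter at a mean of 20 counts and non-robust priors each left 0.

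In the libraries labelled atrial, no gene of 5502 passed edgeR's test, with 674 at an unadjusted p under 0.05. DESeq2 called 132 genes and limma-voom 0. The smallest p was that of Rgs2, at 26.4 ± 3.94 CPM in 3 controls and 83 ± 29.9 CPM in 4 nanoplastics libraries (SD; log2 value 1.63, SE 0.29, adjusted p = 0.204). The next were the autophagy gene Wipi1 (-1.09, SE 0.22, adjusted p = 0.303), Neat1 (-1.17) and Luzp1 (-1.08). Then came the mitochondrial protease gene Afg3l2 (-1.03), the growth factor gene Vegfa (-1.17), the hexokinase gene Hk1 (-1.24) and the pseudogene loci Gm4149 (1.34), Gm11808 (0.69) and Rpl15-ps3 (1.49), from Neat1 on with an adjusted p of 0.305. Nppa had 4.71 (SE 2.78, adjusted p = 0.586) with mouse 1 at 27030 CPM. Of 55 ribosomal genes none passed over all genes but 39 rose adjusted over the list alone (camera adjusted p = 3.91e-24), and of 76 nuclear oxidative phosphorylation genes none passed and 4 rose, Cox6a2, Ndufa3, Ndufb4 and Ndufv3 (3.97e-11; fry adjusted p = 0.0418). Both lists had an adjusted p of 0.937 with an estimated correlation, and with the length trend removed 0.00539 and 0.709. They were the 2 lists of 30 called, and this count was 5, 4 and 7 without control mice 1 and 2 and nanoplastics mouse 4. The control atrial libraries had 1743 nt as the mean of their median annotated lengths per count against 1495 nt in the nanoplastics libraries. The gene count was 1 without control mouse 1 or nanoplastics mouse 2.

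Against the left ventricle, atrial sections had more Col1a2, a fibrillar collagen gene (31.5 ± 12.9 against 12.2 ± 6.09 CPM, SD, n = 7 mice; log2 change 1.34, SE 0.22, adjusted p = 0.0165 by edgeR). They also had more of the endocytic receptor gene Lrp1 (1.29, SE 0.26), of complement C3 (1.07, SE 0.20), Mustn1 (0.98, SE 0.20), the protease inhibitor gene Timp3 (0.96, SE 0.18), App (0.85, SE 0.16), Igfbp7 (0.80, SE 0.15) and Sparc (0.60, SE 0.11). These 8, all higher, were the calls of 5176 genes (652 at an unadjusted p under 0.05). Extracellular matrix genes rose with 2 of 13 called, Col1a2 and Sparc, and 10 adjusted over the list alone (camera adjusted p = 1.18e-12). Macrophage (7 of 11, such as C1qb and Mrc1, adjusted over the list alone; 1.07e-05) and fibroblast markers (6 of 9, such as Dpt and Pi16; 5.48e-05) had none called over all genes. Smooth muscle genes had 1 of 7 called, Mustn1, and 3 adjusted over the list alone (0.0206), and mitochondrially encoded genes were lower with none of 8 called and 6 adjusted over the list alone (3.75e-05). All 13 called lists, 8 higher and 5 lower of 29, lost the call with an estimated correlation (smallest adjusted p = 0.379). The other called lists were higher for atrial markers (0.0225), lysosome (0.0148), glycolysis (0.029) and ribosomal proteins (0.0244), and lower for oxidative phosphorylation (0.00198), erythroid (0.0148), fatty acid oxidation (0.0244) and p53 genes (0.0425), each with no gene called. The medians of oxidative phosphorylation, fatty acid oxidation and p53 genes, -0.08, -0.09 and -0.10, turned to 0.03, 0.02 and 0.02 with library totals alone, which put the median of all genes at 0.12. The gene count was 0 without control mouse 1 and nanoplastics mice 2 or 3, and 98 without nanoplastics mouse 4, and the list count 8 without control mouse 2 or nanoplastics mouse 3. The matrix, macrophage, fibroblast, mitochondrially encoded and oxidative phosphorylation calls held without any single mouse. The largest adjusted p with a mouse left out was 0.784 for fatty acid oxidation and, with the direction turned to lower, 0.247 for ribosomal proteins (nanoplastics mouse 1), 0.148 for p53 and 0.0711 for lysosome genes (nanoplastics mouse 3), 0.127 for glycolysis (control mouse 2), 0.0818 for atrial markers (nanoplastics mouse 1), and 0.0722 for erythroid and 0.0962 for smooth muscle genes (nanoplastics mouse 4).

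Against the right ventricle, atrial sections had more Myl9, a smooth muscle myosin light chain (82.7 ± 66 against 22.1 ± 10.8 CPM, SD, n = 7 and 6 libraries; log2 change 1.58, SE 0.20, adjusted p = 5.31e-09 by edgeR). Right ventricular levels leave out the library of 4662 counts here too, while fold changes include it. Mgp, the matrix Gla protein gene, was higher too (650 ± 458 against 247 ± 69.2 CPM; 1.14, SE 0.16, adjusted p = 3.46e-07). Hemoglobin transcripts were lower, Hbb-bt at 42.3 ± 35.9 against 119 ± 66.1 CPM (-1.42, SE 0.17, adjusted p = 3.27e-10) and Hbb-bs (-1.47, SE 0.25), as was Gpr22 (-0.70, SE 0.17). Further rises were in Ltbp4 (1.60, SE 0.27), C4b (1.45, SE 0.30), Tpm2 (1.27, SE 0.24), Nupr1 (1.17, SE 0.20), Prelp (1.11, SE 0.28) and Serpinf1 (1.07, SE 0.21). In all, 26 genes were higher and 4 lower of 4954 (360 at an unadjusted p under 0.05). Of 6 erythroid genes 2 fell, 4 adjusted over the list alone (camera adjusted p = 9.92e-12; adjusted p = 0.123 with an estimated correlation). Of 14 matrix genes 2 rose, Col1a2 and Postn, 10 adjusted over the list alone (1.03e-09; 0.19 with an estimated correlation). Of 9 fibroblast markers 1 rose, Gsn, 6 adjusted over the list alone (2.21e-06), and of 5 atrial markers Kcnj5 rose, with Kcnj3, Myl7 and Pam added over the list alone (4.54e-05). Other higher lists were ribosomal proteins (9.92e-12), macrophages (5.36e-05), oxidative phosphorylation (0.00353), smooth muscle (0.0121; fry adjusted p = 0.0169), endothelium (0.02) and inflammatory signalling (0.0483), and the smallest adjusted p with an estimated correlation over the 29 lists was 0.123. The count of 30 genes was 92 without nanoplastics mouse 4, 3 without mouse 2, 13 without mouse 1 and 5 without the library of 4662 counts and the atria of nanoplastics mouse 1; DESeq2 called 11 and limma-voom 4. Without these libraries the adjusted p was 0.583 for ribosomal proteins, 0.369 for inflammatory genes and, with the direction turned to lower, 0.369 for oxidative phosphorylation. With a mouse left out it was at most 0.203 for endothelium (control mouse 2), 0.253 for inflammatory genes (nanoplastics mouse 1), 0.0759 for smooth muscle (nanoplastics mouse 4) and, with the direction turned to lower, 0.0893 for oxidative phosphorylation (nanoplastics mouse 2).

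Between the ventricles, Hbb-bt was higher in the right, at 115 ± 63.8 CPM without the library of 4662 counts against 79 ± 42.7 CPM (SD, n = 6 and 7 libraries; log2 change 0.74, SE 0.14, adjusted p = 0.00413 by edgeR). It was the single call of 5012 genes, with 261 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Nuclear oxidative phosphorylation genes were lower in the right ventricle as a list (median -0.11 over 76 genes, none called, camera adjusted p = 5.14e-13). So were mitochondrially encoded (0.00019), fatty acid oxidation (0.000385), ribosomal (0.000812) and tricarboxylic acid cycle genes (0.0304), and intercalated disc and erythroid genes were higher (both 0.0181). None of the 28 lists held with an estimated correlation (smallest adjusted p = 0.73), and the ribosomal median of -0.06 became 0.02 with library totals alone. The gene count was 0 without nanoplastics mouse 2, 5 without control mouse 3 and 2 without nanoplastics mouse 1 or 3, and the list count 4 without control mouse 2. The oxidative phosphorylation call held without any single mouse. The largest adjusted p with a mouse left out was 0.856 for ribosomal and 0.151 for intercalated disc genes (control mouse 1), 0.0603 for fatty acid oxidation and 0.134 for erythroid genes (control mouse 2), and 0.1 for mitochondrially encoded and 0.223 for tricarboxylic acid cycle genes (nanoplastics mouse 2).

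The nanoplastics effect was not shown to differ between sections. No gene of 6269 passed the interaction test of edgeR, with 287 at an unadjusted p under 0.05, and DESeq2 called 1. The smallest adjusted p was 0.539 for Xirp2, an intercalated disc gene, followed by the antigen presentation gene H2-Aa, Lpar6 and mt-Tm (0.79) and by Matr3, Abcf3, Glmp, Afg3l2, Zfyve9 and Ranbp2 (0.859). The effect on Xirp2 differed by -1.15 on the log2 scale between atria and left ventricle (SE 0.26, adjusted p = 0.208). That on H2-Aa differed by 1.18 between atria and right ventricle (SE 0.29, adjusted p = 0.323) and that on Socs2 by -1.27 between the ventricles (SE 0.35, adjusted p = 0.894). In these contrasts of section pairs edgeR called no gene, with 345, 317 and 188 at an unadjusted p under 0.05, and DESeq2 called 1, 0 and 0. As a list, ribosomal proteins had a larger effect in the atria than in the left ventricle (median difference 0.27 over 55 genes, camera adjusted p = 1.8e-07) and than in the right (0.15, 0.000413). Intercalated disc genes had a lower one (-0.28 over 16 genes, 0.0122, and -0.17, 0.00501), with adjusted p of at least 0.827 with an estimated correlation. The other lists called were sarcomere and calcium handling (both 0.0253) and erythroid genes (0.0122), lower in the atria than in the left ventricle, oxidative phosphorylation (3.02e-06), higher in the atria than in the right ventricle, and calcium handling (0.0421), oxidative phosphorylation (0.00221) and tricarboxylic acid cycle genes (0.00882), lower in the right than in the left ventricle. None held with an estimated correlation either (smallest adjusted p = 0.827, 0.95 and 0.928 for the 3 pairs). The interaction count was 2 without control mouse 3 or nanoplastics mouse 4 and 1 without nanoplastics mouse 2.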

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

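The tests of the length trend, of the atrial-rich libraries, of exchanged labels, of a shared response and of other splits were chosen after the results they bear on had been seen, and the test of the right ventricle after its count of called genes was known.

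The first pattern is the whole-heart rise of genes with short annotated transcripts. It could come from RNA or library quality, or from the mix of sections in the sums, as well as from treatment. With each library's trend on transcript length removed, the risers kept 49.6% of their median log2 change (0.603 before and 0.299 after, 95% interval 43.8 to 56.7% over bootstrap draws of genes), and 13 of 152 stayed past the threshold, while the genes that fell kept 98.6% and 19 of 65 stayed; since the trend is fitted partly on the short genes that rose, it may remove real change, and the explanation stays open. Atrial muscle in some nanoplastics libraries is argued against as the main source, since without the 3 atrial-rich libraries the risers kept 97% of their median (94.2 to 99.8%), although only 20 stayed past the threshold with fewer counts per mouse. The interval covers draws of genes and not differences between mice, and nanoplastics mouse 4 then rests on its right ventricle alone. The dissection covariate ended the whole-heart calls, which this test does not explain. Chance as the sole source of the 217 calls is argued against, as the real grouping is the 1 of 35 splits of the mice with that many. The highest other split gave 10. Chance is not excluded, since 1 of 35 is the smallest share that 7 mice allow and is not adjusted over the comparisons. Length trend and treatment separate the mice in the same way here, and so do the section shares of the sums. The right ventricle gave 36.48 to 43.95% of a control's counts and 0.1995 to 27.91% of a nanoplastics mouse's. Annotated lengths were also shorter within the atria (1495 against 1743 nt) and left ventricle (1530 against 1672 nt), where these shares do not enter. A nanoplastics response could account for the rise but cannot be told apart from the length trend. For the calls on summed counts it cannot be told apart from the mix of sections either. The length trend itself is read from the same counts by annotated length and is no separate measure of RNA quality.

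The second pattern is the scarcity of atrial transcripts in most libraries labelled atrial section. An exchange of section labels within a mouse is argued against, since the highest summed level of Myl7, Myl4 and Sln in the ventricular libraries of the 5 mice concerned was 41.1 CPM, and the library of 4662 counts among them, with none, allows at most 643.5 CPM, both under the 1000 CPM that an exchange would need. The scarcity is not confined to treated mice, since the control atrial libraries had sums of 19.94, 296.7 and 52.86 CPM. The test of a shared response to nanoplastics asked only about a rise of the sum in the treated mice. Such a rise in all of them is argued against, since only 2 of the 4 nanoplastics atrial libraries lay above the highest control. The medians were 1518 and 52.86 CPM (exact permutation p = 0.429, n = 4 and 3). A section that took mostly ventricular tissue would likely look like this, but no test here addresses it, and the small amounts in the left ventricle of nanoplastics mouse 4 may be atrial tissue as well.

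The third pattern is the set of right ventricular calls, where 1 library has 4662 counts. All 39 called genes kept their direction and at least 50% of their log2 change without it, but this decides nothing, although it meets what was written beforehand: the library holds a median of 1.11% of the nanoplastics libraries' weight in the fit, so its removal could hardly move a fold. Its share in the calls stays open, since 23 of the 39 were called again without it, and DESeq2 and limma-voom went from 0 calls to 172 and 79. Chance cannot be excluded, since 3 of 35 splits gave as many calls and the highest other split gave 157 against the real 39, which points to a structure of the samples that was not identified. A nanoplastics effect in the right ventricle may exist, but the groups also differ in depth, 444800 against 1722000 counts, and no value here tells treatment and depth apart.

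For the other counts, 5 of 35 splits gave as many calls in the left ventricle (real 3, highest other 38), so chance cannot be excluded there. The atria (0 and 11) and the interaction (0 and 17) had no calls, so 35 of 35 splits reach the real count by construction and decide nothing. Exchanging section names within mice gave as many calls in 3 of 64 ways between atria and left ventricle (8 and 106), in 4 of 64 between atria and right ventricle (30 and 116) and in 24 of 64 between the ventricles (1 and 8). The share of such ways was under 5% only for atria against left ventricle. It is not adjusted over the section pairs and was chosen after the results were seen, so chance is not excluded for any pair. The splits with several times the real count point to a structure of the samples.

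Dixon's test singled out 11 of 109 groups of 4 nanoplastics values (10.1%) in which a sample lay far from the others. Chance flags about 1 in 20 groups. In the atria, mouse 1 had the shortest median annotated length per count, 1318 nt with the nearest at 1549 nt, and the highest Myl7, Myl4 and Sln sum, 38990 against 2969 CPM, and Nppa, 27030 against 244 CPM. Mouse 1 also had the highest whole-heart Nppa, 7998 against 362.4 CPM. Vegfa in the atria was highest in mouse 3, 18.24 against 10.98 CPM. In the right ventricle mouse 2 had the fewest genes detected, 1462 against 10100, and no Pfdn2 count, 0 against 13.85 CPM, where its floor is 643.5 CPM. Mouse 4 had the highest sum of the 3 atrial transcripts in the right ventricle, 100.4 against 9.559 CPM, and in the left, 1605 against 13.45 CPM, and the highest left ventricular Nppa, 659.3 against 159.1 CPM. Art5 in the whole heart was lowest in mouse 2, 0.462 against 2.87 CPM.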

How the results depend on the processing

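The alternatives without the lowest-count library, without the 2 doubted libraries, without the 3 atrial-rich libraries, without robust priors, with the length trend removed, and the list tests with a mouse left out or with equal weights were tests chosen after the data were seen. At the real depths, 49% of simulated 2-fold changes were recovered in the atria, 61% in the right and 65% in the left ventricle. The cause was not tested unless fewer samples or genes show it. In the whole heart the 217 calls stayed within 1.5 times under DESeq2 size factors (208), no filter (319), limma-voom (148), removal of mitochondrially encoded genes (197) and the block by mouse number (313), whose numbers name different animals (of 8 same-number pairs 1 had a correlation of deviations from group means over 0.1, range -0.239 to 0.167). They became 797 (43 higher, 754 lower) with library totals alone, 369 with DESeq2, 0 with the dissection covariate and with equal weights, 38 with the length trend removed, 23 without the atrial-rich libraries and 91 without robust priors. Leaving out a mouse gave 0 to 201. The right ventricular 39 became 73 (25 higher, 48 lower) with DESeq2 size factors, 234 (11 and 223) with totals alone, 20 without a filter, 61 at a mean of 20 counts, 0 with DESeq2 and limma-voom (172 and 79 without the lowest-count library), 4 with the number block, 3 with the covariate and 3 in a fit of all 21 libraries, leave-one-out 4 to 175. The left ventricular 3 became 23 (all lower) with totals alone, 30 without a filter, 155 with DESeq2, 1 in the fit of all libraries, and 0 at a mean of 20 counts, without mitochondrially encoded genes, with the number block and without robust priors, leave-one-out 0 to 21. The atrial 0 became 17 without a filter, 132 with DESeq2 and 106 with the number block, leave-one-out 0 to 1.

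Atria against left ventricle, 8 calls, gave 42 with totals alone, 115 without a filter, 0 without the mouse block and 17 in controls, leave-one-out 0 to 98. Atria against right ventricle, 30, gave 10 with totals alone, 65 without a filter, 17 at a mean of 20 counts, 11 with DESeq2, 4 with limma-voom, 0 without the mouse block, 11 in controls, 17 in nanoplastics mice and 5 without the doubted libraries, leave-one-out 3 to 92. The ventricles, 1, gave 2 without a filter and 0 with totals alone, at a mean of 20 counts, with DESeq2, limma-voom, no mouse block, controls only and without the doubted libraries, leave-one-out 0 to 5. The interaction, 0, gave 1 with DESeq2 and without the doubted libraries, leave-one-out 0 to 2; between atria and left ventricle 1 without a filter, at a mean of 20 counts, with DESeq2 and without the doubted libraries, leave-one-out 0 to 3; leave-one-out 0 to 2 between atria and right ventricle and 0 to 1 between the ventricles. Called lists fell to 0 with an estimated correlation in all 7 comparisons, and with fry in all but the atria (1 of 2) and atria against right ventricle (1 of 10). The 2 atrial lists became 4 with the covariate and 4 with the length trend removed (leave-one-out 2 to 7), the right ventricular 1, higher, became 5, all lower, with the covariate, 0 with the length trend removed and 4 without the doubted libraries (leave-one-out 1 to 4), the left ventricular 5 became 0 with the length trend removed (leave-one-out 4 to 7), and the whole-heart 8 became 5 with the covariate (which is built from atrial and ventricular markers, so the loss of the atrial and sarcomere lists there decides nothing) and 5 without the doubted libraries (leave-one-out 6 to 12), and stayed at 8 with equal weights, with erythroid genes in place of fibroblasts. Leave-one-out list counts were 8 to 13, 8 to 12 and 4 to 8 in the section pairs.

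Of 2820 values of 148 named gene results under alternatives, 1945 stayed, 787 lost the call, 42 gained it and 46 reversed, nearly all in genes without a call. Ptov1 in the right ventricle had -0.163 with the covariate. The others are whole-heart log2 values: with totals alone Nppb -0.23, Cacna1c -0.238, Ryr2 -0.159, Atp2a2 -0.103, Pln -0.186 and Postn -0.141; without a filter Nppb -0.001 and Cacna1c -0.012; at a mean of 20 counts Cacna1c -0.004; with the number block Cacna1c -0.026, Ryr2 -0.11 and Atp2a2 -0.029; with the covariate Nppa -0.457, Cacna1c -0.04 and Pln -0.033, where Nppa and Pln are part of the covariate. With equal weights Nppb had -0.217, Cacna1c -0.413, Ryr2 -0.494, Pln -0.137 and Postn -0.274, while the median of all genes moved to -0.3 (-0.271 with totals alone), so a shift shared by all genes enters these signs. The library of 4662 counts, where most genes have no count, also weighs as much there as the other sections of its mouse. Further values were, with mouse as a random effect, Nppb -0.101, Pln -0.142 and Postn -0.176. Without the doubted libraries Nppb had -0.083, Kcnj2 0.021 and Postn -0.037, with the length trend removed Nppb -0.306, and without the atrial-rich libraries Nppb -0.072, Kcnj2 0.121 and Cacna1c -0.002. Leave-one-out ranges were -0.197 to 0.238 for Nppb, -0.412 to 0.041 for Kcnq1, -0.179 to 0.084 for Kcnj2, -0.086 to 0.115 for Cacna1c, -0.12 to 0.215 for Ryr2, -0.026 to 0.239 for Atp2a2 and -0.205 to 0.29 for Postn.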

Other observations

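The tests on matched genes, nuclear RNAs and mouse likeness were chosen after the whole-heart results had been seen. Against random lists of genes matched in length and expression, extracellular matrix genes had a whole-heart median of 0.33 where the random median was -0.07 (percentile 100 over 10000 lists), and fibroblast markers 0.24 against -0.05 (percentile 99.94). Random lists ignore correlation within a list: both had an adjusted p of 0.501 with an estimated correlation, and 0.173 and 0.121 without the 2 doubted libraries. The p53 and apoptosis genes had -0.39, where the 5th percentile of random lists was -0.17, but their adjusted p was 0.501 with an estimated correlation, 0.0731 without control mouse 1 and 0.157 with the dissection covariate. Sarcomere genes were at percentile 76.87 and mitochondrially encoded genes at 20.91.

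Markers of brown fat were uneven. Ucp1, the heat-producing uncoupling protein, had at most 55.07 CPM in the atria against 0.5918 CPM in the left and 1.912 CPM in the right ventricle, with medians of 0 in each. Cidea, another brown fat marker, had medians of 45.57, 40.18 and 43.53 CPM in atria, left and right ventricle. The fat hormone gene Adipoq had at most 24.69 CPM in the atria. Upk3b, a gene of the outer lining of the heart, had a median of 4.394 CPM in the atria, 0 in the left and 0.7501 CPM in the right ventricle.

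A first hypothesis was that ribosomal protein genes rose in the whole heart beyond other genes of their length and expression. Their median of 0.51 lay at percentile 100 of matched random lists, whose median was 0.24 (0.177 to 0.314 between the 5th and 95th percentiles), which length and expression alone do not give in random lists. These ignore correlation within a list, and with an estimated correlation the adjusted p was 0.563, so the hypothesis stays open. The same hypothesis for nuclear oxidative phosphorylation genes is argued against, as their median of 0.36 was at percentile 77.59 of matched lists. A further hypothesis was that nuclear-retained RNAs fell as a class, as Neat1 did. The 15 such RNAs without a call had a median of -0.16, at percentile 10.77 of matched lists. This meets what was written beforehand for no class effect, but called genes had been left out of the list, so it excludes nothing and the question stays open.

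Libraries of the same mouse resembled each other in their deviations from the mean of their treatment and section group. Over 3712 genes and 20 libraries, these deviations had a mean correlation of 0.271 between sections of a mouse. It was -0.106 between different sections of different mice of a treatment. Taking out the means of groups this small pulls the value between mice below 0, so its sign has no meaning. The difference was 0.377 (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). This is consistent with differences between mice that all sections share, whether from the animals or from handling.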
